A study of Mus musculus with 2 samples.

How the data were processed

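Total RNA was taken from cultured B16 and B16/BL6 mouse melanoma cells, and libraries were made with a stranded Illumina mRNA kit, per the labels' protocols. There was 1 library of each line, and the growth media differed between the lines (DMEM for B16, RPMI for B16/BL6). The deposited values are FPKM per the file headers, with 1 value per gene symbol. FPKM is fragments per kilobase of transcript scaled to the mapped fragments of the library, but the headers do not state the scaling used. The submitters' processing notes name TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19, Cufflinks 2.2.1 and the mm10 build, without their order or settings. The gene annotation, the handling of reads that map to several places, bias correction and read counts are not given in the sources used here. Both files list the same 23284 symbols, each once, of which 9351 were at 0 in both libraries. Mitochondrial genes were not analysed here.

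FPKM is not a count, so no count test was run, and with 1 library per line no test between the lines was possible. The difference of a gene is log2(FPKM + 1) in B16/BL6 minus that in B16, with a pseudocount of 1. Genes at 1 FPKM or more in at least 1 library were used (10709 genes), and a gene was counted as higher or lower at 2-fold. A value listed at 0 can be a failed estimate, and no ratio is given against it. FPKM of features shorter than a sequencing fragment is poorly estimated: microRNA and other small RNA symbols held 8.75% of the FPKM sum in B16 and 8.31% in B16/BL6. The sums were 500485 and 563451.

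Relative depth was read from the low values. Among 379 genes above 0 and below 0.1 FPKM in both libraries, 155 had the same ratio of B16/BL6 to B16, 0.906, and 86.8% had this ratio times a ratio of whole numbers up to 5, within 0.5%. If each library was scaled to its own mapped fragments, a ratio of 0.906 for equal fragments means a depth 1.10 times higher in B16/BL6. The absolute depth was estimated from genes under 0.2 FPKM with a single annotated transcript longer than 1500 bases, taking estimates from 8 to 14 times 1000000 fragments as those of genes with 1 fragment. That range was set after the spread of the estimates had been seen. The medians were 9976989 fragments in B16 (23 genes) and 11136359 in B16/BL6 (29 genes). It is an approximation, since the authors' effective lengths are not recorded, and no interval or floor was derived from it.

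Before the data were examined, the design, the alternatives, the rule for naming genes and 32 gene lists (pigmentation, melanoma states, adhesion, immune, growth, metabolism, quality and markers of other cell types) were fixed. The rule named the 12 genes with the largest difference in each direction among those at 5 FPKM or more in at least 1 library, leaving out predicted and clone-named genes, small RNAs, ribosomal protein pseudogenes and antigen receptor segments, up to 4 members of each list with the largest differences (a few are not reported here), and 8 genes whatever their values (Mitf, Tyr, Mlana, Met, Cdh1, Cdh2, Axl and Actb). A few further genes were named after their values were seen: Snora78, Gapdh, B2m, Col1a1, Col3a1, Dcn, Lum, Ptprc and Pecam1 in the results, and the genes of the closing observations. For each list with at least 5 members past the minimum, the median difference was set among the medians of 10000 random lists of the same size, drawn from genes in the same one of 20 bins of mean log2 value. The percentile describes these libraries and is not a p-value. Some genes are in more than one list.

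Gene positions came from the RefSeq annotation of GRCm38, the assembly that mm10 names, by symbol or by a synonym that a single gene carries. This placed 22996 of the symbols, and 10629 of the 10709 expressed ones. Windows of 40 consecutive expressed genes, in steps of 10 genes, were compared with 100 shuffles of gene order. Transcript length, GC content and overlapping genes came from GENCODE M21. The trends on GC content and length were removed as the medians of 20 bins of each. A limit tried after the corrected medians were known, that the amounts removed have a standard deviation of at least 0.05, was missed (0.044) and would have left the test undecided. It was dropped for the criterion written before the test, that the median of chromosome 10 stay at 0.2 or more.

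On simulated data with B16 levels, the procedure recovered 100% of 200 genes changed by 2 on the log2 scale, put a list shifted by 0.5 at the 100th percentile and gave 0.31 for a chromosome shifted by 0.4, with 0.06 for the farthest other chromosome. The changed genes were at 5 FPKM or more in B16 and carried no noise, so their recovery was set in advance. The other genes had independent normal noise with a standard deviation of 0.4. In the data the standard deviation by level was 0.41 to 0.85, real differences included. In 40 simulations without changed lists, 3.76% of 1063 list medians fell in the lowest or highest 2.5%. In the simulation with changed genes, 4 of 24 other lists did so. The shifted chromosome held members of some of these lists, and the changed genes were drawn without sparing them. The 4 of 24 is therefore not a rate for unchanged lists. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The alternatives were pseudocounts of 0.1 and 5, no expression minimum or one of 5 FPKM, the TPM scale, scaling to the median ratio or the upper quartile, leaving out predicted genes and small RNAs, unmatched random lists and windows of 20 or 80 genes. After each scaling the minimum and the pseudocount of 1 were applied to the scaled values, so the genes and list members that pass can differ. Summing or choosing among rows of one symbol did not apply, since no symbol was repeated. Centring each chromosome at its own median was added after the data were seen.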

Results

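The transcriptomes of 2 mouse melanoma cultures were measured by RNA sequencing, to search for genes related to metastasis. B16 is a melanoma line that arose in a C57BL/6 mouse, and B16/BL6 is an invasive subline derived from it. There was 1 library of each line, so no value below has a replicate error, no difference between the lines was tested, and no p-value is given. The lines were also grown in different media, DMEM for B16 and RPMI for B16/BL6, so the line and the medium cannot be told apart. Expression was given in FPKM for 23284 gene symbols per library. In B16, 10413 genes reached 1 FPKM and 893 reached 100 FPKM. In B16/BL6 these numbers were 10367 and 978. The depth was not recorded, but the lowest values moved in steps of single fragments, which put the B16/BL6 library at 1.10 times the depth of the B16 library as a rough estimate. By an approximate estimate of the absolute depths, a transcript of 2 kb at 1 FPKM rested on about 20 fragments in B16 and 22 in B16/BL6.

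The comparison of B16/BL6 with B16 asked which genes differ between the parental line and its invasive subline. Several small RNA genes differed most, but values of such short features are poorly estimated and they were not named. Among the genes that could be named, the largest difference was that of Mbp, which encodes myelin basic protein (chromosome 18, 82475091 to 82585637, in mm10 coordinates as below), at 1.45 FPKM in B16 and 620 FPKM in B16/BL6, a ratio of 427. Tyr, which encodes tyrosinase, the rate-limiting enzyme of melanin synthesis (chromosome 7, 87424771 to 87493512), stood at 10.6 and 164 FPKM. The receptor tyrosine kinase gene Kit (chromosome 5, 75574987 to 75656722) stood at 0.457 and 21.9 FPKM. In the other direction, the actin-binding protein gene Tagln2 (chromosome 1, 172500246 to 172507375) was at 151 FPKM in B16 and 0.210 FPKM in B16/BL6, the chemokine gene Ccl5 (chromosome 11, 83525778 to 83530518) at 40.4 and 1.02 FPKM, and the calcium-binding protein gene S100a4 (chromosome 3, 90603770 to 90606045) at 57.9 and 2.54 FPKM.

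Of 10709 genes at 1 FPKM or more in at least 1 library, 354 were at least 2-fold higher in B16/BL6 and 338 at least 2-fold lower, on the log2(FPKM + 1) scale, which understates the change of low genes. At least 4-fold differences were found for 82 genes that were higher and 65 that were lower. The remaining 10017 genes, 93.5%, lay within 2-fold. Spearman's rho across the 10709 genes was 0.947, and genes are not independent replicates. Rescaling each library to a sum of 1000000 (the TPM scale) shifted the median log2 difference of all genes by -0.16 and turned the split into 369 genes higher and 583 lower. The minimum and the pseudocount of 1 were applied again to the rescaled values, so 11257 genes were considered. Counts and list medians on that scale therefore do not come from rescaling alone, and the list members that pass can differ. The log2 differences had a standard deviation of 0.85 among genes averaging under 5 FPKM, 0.61 from 5 to 20 FPKM, 0.64 from 20 to 100 FPKM and 0.41 from 100 FPKM. These include real differences between the lines as well as measurement error.

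Among the other 9 genes with the largest differences toward B16/BL6, the choline transporter-like gene Slc44a3 stood at 0.501 FPKM in B16 and 59.6 FPKM in B16/BL6. The small heat shock protein gene Hspb8 stood at 0.0565 and 26.6 FPKM, and Prr5, which encodes a component of the mTORC2 kinase complex, at 0.111 and 26.7 FPKM. Pla2g2e, a secreted phospholipase A2 gene, was at 7.04 and 134 FPKM, and Nqo1, a quinone reductase gene and a target of the oxidative stress factor Nrf2 (chromosome 8, 107388225 to 107403205), at 1.75 and 44.5 FPKM, a ratio of 25.4. C1ql3 was at 0.0668 and 12.9 FPKM. Adm, which encodes adrenomedullin, the glycosyltransferase gene Galnt6 and the noncoding Snhg9 were listed at 0 in B16 and at 35.3, 16.8 and 14.1 FPKM in B16/BL6. Snhg9 hosts the small nucleolar RNA Snora78, which was listed the other way round, at 29.9 FPKM in B16 and 0 in B16/BL6.

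Among the other 9 genes with the largest differences toward B16, Fkbp11, a peptidyl-prolyl isomerase gene of the secretory pathway, stood at 48.9 FPKM in B16 and 0.311 FPKM in B16/BL6, and Isyna1, the inositol phosphate synthase gene, at 39.3 and 0.151 FPKM. Dpysl3 was at 22.6 and 0.277 FPKM, and Pafah1b3, a catalytic subunit gene of platelet-activating factor acetylhydrolase, at 21.6 and 0.372 FPKM. Hapln1, which encodes a link protein between hyaluronan and proteoglycans, was at 18.7 and 0.220 FPKM. Fam178b was at 41.0 and 1.80 FPKM, and the lectin pathway protease gene Masp1 at 16.8 and 0.516 FPKM. The X-linked genes Foxr2 and Taf9b were at 12.9 and 11.1 FPKM in B16 and were both listed at 0 in B16/BL6. An abundant control, Actb, was at 1789 and 1747 FPKM.

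**Figure D1:**
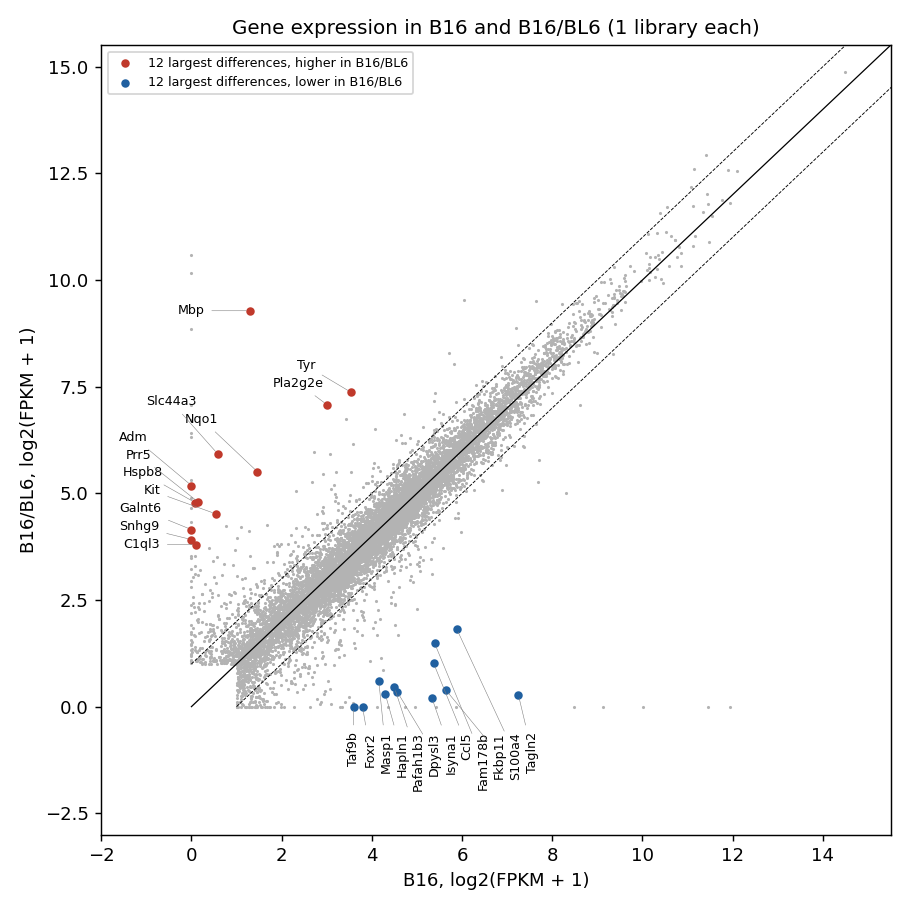
Expression of the 10709 genes at 1 FPKM or more in at least 1 library, as log2(FPKM + 1) in B16 (x axis) and B16/BL6 (y axis), 1 point per gene; the solid line marks equality and the dashed lines a 2-fold difference. The 12 named genes with the largest differences in each direction are coloured, with Mbp at 620 FPKM in B16/BL6 and Tagln2 at 151 FPKM in B16 farthest from the diagonal.

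Several pigment genes were higher in B16/BL6. Of 21 measured genes of pigment synthesis and the melanosome, 4 were at least 2-fold higher in B16/BL6 and 0 at least 2-fold lower. These 4 were Kit, Tyr, the cation channel gene Trpm1 (40.7 FPKM in B16 and 142 in B16/BL6) and Pmel, which encodes the fibril protein of the melanosome (2166 and 4651 FPKM, a log2 difference of 1.10). Pmel lies on chromosome 10 and was under 2-fold on the TPM scale (0.93) and with each chromosome centred (0.69), which left 3 genes higher. Mlana, the gene of the melanoma antigen Melan-A, was at 3789 and 6160 FPKM. Mitf, the master transcription factor of melanocytes, was at 97.1 and 90.7 FPKM, and Met, the hepatocyte growth factor receptor gene, at 49.7 and 69.0 FPKM. The median log2 difference of the list was 0.29, at the 97.6th percentile of 10000 random lists matched on expression, and 0.13 (97.4th percentile) on the TPM scale. The 8 measured genes of the undifferentiated or invasive melanoma state had a median of -0.28 (5.16th percentile). The list's median was -0.73 (0.21st percentile) on the TPM scale, -0.33 (0.40th percentile) without an expression minimum and -0.54 (0.39th percentile) with a minimum of 5 FPKM, but -0.14 (18.3rd percentile) with each chromosome centred at its own median. The TPM scale and the other minima can let other members of the list pass, so those medians need not be of the same 8 genes. The 8 genes included the receptor gene Pdgfrb (0.104 and 7.43 FPKM), the intermediate filament gene Nes (58.8 and 22.2 FPKM) and the receptor tyrosine kinase gene Axl (5.77 and 12.4 FPKM). Of 8 neural crest and Schwann cell genes, 1 was at least 2-fold higher in B16/BL6, the myelin gene Pmp22 (25.2 and 115 FPKM), and 2 were lower, among them the adhesion molecule gene L1cam (10.8 and 4.70 FPKM), and the list's median was -0.11 (14th percentile). With each chromosome centred it was -0.26 (1.13th percentile).

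Genes of the epithelial-mesenchymal transition differed in both directions. Of 12 measured members, 1 was at least 2-fold higher in B16/BL6 and 3 lower, with a median of -0.07 (26.2nd percentile), or -0.31 (14.6th percentile) on the TPM scale. S100a4, Tgfb1 (7.11 and 0.522 FPKM in B16 and B16/BL6) and Tgfb2 (1.80 and 0.363 FPKM), the last 2 encoding transforming growth factors, were lower, and the osteopontin gene Spp1 (0.523 and 3.18 FPKM) was higher. The N-cadherin gene Cdh2 was at 31.2 and 34.3 FPKM, and the E-cadherin gene Cdh1 was close to 0 in both libraries, at 0.108 and 0.0976 FPKM.

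Adhesion and matrix genes differed gene by gene. Among 17 other cell adhesion molecules, 4 were at least 2-fold higher in B16/BL6 and 4 lower. The tetraspanin gene Cd82, a metastasis suppressor, was at 3.97 FPKM in B16 and 32.0 FPKM in B16/BL6, and Bcam, a laminin-binding receptor gene, at 2.18 and 9.44 FPKM. Mcam, the melanoma cell adhesion molecule gene, was lower in B16/BL6, at 204 and 37.5 FPKM, and the junction gene F11r was at 1.71 FPKM in B16 and listed at 0 in B16/BL6. The median of this list was 0.31 (99.1th percentile), although as many members passed 2-fold downward as upward, and it was 0.14 on the TPM scale, 0.17 without an expression minimum and 0.49 with a minimum of 5 FPKM. Of 9 integrin genes, 1 was at least 2-fold higher, Itga9 at 2.52 and 9.5 FPKM, and 0 were at least 2-fold lower, or 1 on the TPM scale. The median was -0.33 (1.44th percentile), but it was at the 3.69th percentile without an expression minimum (-0.11), the 6.75th with a minimum of 5 FPKM (-0.23) and the 3.82nd on the TPM scale (-0.40). Members included Itga6 at 52.0 and 30.7 FPKM and Itga5 at 12.8 and 8.01 FPKM. Itga1, at 4.16 and 2.03 FPKM, had a ratio of 2.05 without the pseudocount and stayed under 2-fold with it.

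Of 16 collagen and matrix glycoprotein genes, 4 were at least 2-fold higher in B16/BL6 and 2 lower. The basement membrane collagen gene Col4a2 was at 0.714 and 17.7 FPKM, Col16a1 at 2.70 and 10.8 FPKM and Col1a2 at 0.367 and 5.32 FPKM, while the laminin gene Lamb1 was at 6.34 and 0.0737 FPKM. The list's median was 0.23 (97.7th percentile), and -0.03 (85.3rd percentile) on the TPM scale. Of 14 fibroblast markers, Pdgfrb and Col1a2 alone reached 1 FPKM, both higher in B16/BL6. The fibroblast genes Dcn, Lum and Col3a1 were listed at 0 in both libraries, and Col1a1 was at 0.161 and 0.110 FPKM. Of 25 matrix proteases and inhibitors, 3 were higher and 3 lower, or 2 and 6 on the TPM scale and 2 and 4 after upper-quartile scaling. The metalloprotease gene Adam12 was at 7.93 and 0.967 FPKM, the urokinase receptor gene Plaur at 23.4 and 9.60 FPKM, Serpinf1 at 15.6 and 6.06 FPKM and Mmp16 at 0.373 and 2.74 FPKM. Their median was 0.02 (49.1th percentile), and -0.15 (49.5th percentile) on the TPM scale and -0.03 (48.3rd percentile) after upper-quartile scaling.

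The list of metastasis promoters and suppressors held members with large differences in both directions. Of 16 measured members, 2 were at least 2-fold higher in B16/BL6, Cd82 among them, and 3 lower. The lower ones were S100a4, Mcam and the galectin-3 gene Lgals3 (chromosome 14, 47373860 to 47386167), at 316 FPKM in B16 and 31.1 FPKM in B16/BL6. The median was 0.23 (95.4th percentile).

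The list of interferon-stimulated genes had a low median. Of its 15 measured genes, 11 were below 0, 0 were at least 2-fold higher and 4 lower, namely Isg15 (7.11 FPKM in B16 and 1.95 in B16/BL6), Ifit1 (1.94 and 0.135 FPKM), Ifit3 (1.67 and 0.321 FPKM) and Ifitm3 (40.6 and 18.3 FPKM), products of the antiviral interferon response. The list's median was -0.47 (0.15th percentile), or -0.72 with 7 genes lower on the TPM scale and -0.54 with 3 lower when each chromosome was centred. Of 13 chemokines and cytokines, 4 were lower and 2 higher, with a median of -0.24 (7.54th percentile), which was -0.53 (1.53rd percentile, 5 lower) on the TPM scale and -0.36 (1.22nd percentile) with each chromosome centred at its own median. Besides Ccl5, the neutrophil chemokine genes Cxcl1 (17.4 and 1.22 FPKM) and Cxcl2 (2.17 and 0.0938 FPKM) were lower. Of 12 genes of MHC class I presentation, 2 were lower and 1 higher. The class I heavy chain genes H2-K1 (chromosome 17, 33996012 to 34000619) and H2-D1 (chromosome 17, 35263094 to 35267497) were at 6.68 and 62.4 FPKM in B16 and at 0.228 and 15.95 FPKM in B16/BL6. H2-Q4 was at 2.29 and 5.90 FPKM. These genes share sequence with one another, and how the authors' counting split such reads is not given in the sources used here. The list's median was -0.04 (37.2nd percentile), and B2m, the light chain gene, was at 445 and 441 FPKM.

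Immediate early genes were lower in B16/BL6 as a list. Of 12 measured members, 0 were at least 2-fold higher and 2 lower, the stress transcription factor gene Atf3 (8.71 FPKM in B16 and 1.25 in B16/BL6) and Ier3 (117 and 32.8 FPKM). The median was -0.62, below every one of the 10000 matched random lists, and 10 of the 12 members were below 0. Without an expression minimum it was -0.28 (0.41st percentile). The 30 cell cycle and DNA replication genes were all within 2-fold. Their median was 0.06 (24th percentile), or -0.11 (24.1st percentile) on the TPM scale. Among these genes, the ribonucleotide reductase gene Rrm2 was at 250.0 and 361 FPKM and the cyclin gene Ccna2 at 99.7 and 141 FPKM. Of 16 p53 targets, 1 was lower, the kinase gene Plk2 at 1.85 and 0.285 FPKM, and the cell cycle inhibitor gene Cdkn1a was at 153 and 103 FPKM. Their median was 0.10 (75.7th percentile), or -0.02 (83.8th percentile) on the TPM scale and 0.36 (99.4th percentile) with a minimum of 5 FPKM. Of 13 genes of MAPK pathway output, 2 were lower, Spry4 (2.94 and 0.412 FPKM) and Etv4 (2.55 and 0.501 FPKM), and 1 was higher, the ephrin receptor gene Epha4 (0.0444 and 2.19 FPKM), with a median of -0.01 (38th percentile). That median was -0.15 (50.4th percentile) on the TPM scale and -0.23 (2.24th percentile) with each chromosome centred. Of 9 angiogenic and growth factors, 2 were lower, Angpt2 (25.5 and 10.0 FPKM) and Tgfa (5.18 and 2.04 FPKM), and the median was 0.20 (89.2nd percentile). It was 0.089 (94.8th percentile) on the TPM scale, 0.096 (78.8th percentile) with a pseudocount of 5 and 0.021 (65.5th percentile) without an expression minimum. Vegfa, the main vascular growth factor gene, was at 16.9 and 10.1 FPKM.

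Genes of the oxidative stress response were higher in B16/BL6 by their median. Of 17 measured members, 4 were at least 2-fold higher, 0 at least 2-fold lower and 16 above 0, with a median log2 difference of 0.545, above every one of the 10000 matched random lists. Besides Nqo1, the 4 higher genes were Osgin1 (15 FPKM in B16 and 51.7 in B16/BL6), the thioredoxin reductase gene Txnrd1 (150.2 and 356 FPKM) and the heme oxygenase gene Hmox1 (40.6 and 87.9 FPKM). The list had 3 genes higher on the TPM scale (median 0.378) and 3 with each chromosome centred (median 0.525). The 22 genes of cholesterol synthesis and uptake were within 2-fold, but 19 of them were above 0, with a median of 0.28 (99.9th percentile), or 0.13 (99.8th percentile) on the TPM scale. Fdft1, the squalene synthase gene, was at 8.61 and 16.4 FPKM, and Insig1, which encodes a sterol sensor of the endoplasmic reticulum, at 22.05 and 36.1 FPKM.

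Genes of the amino acid response, hypoxia response and glycolysis were lower in B16/BL6 by their medians. Of 24 genes of the amino acid response and serine synthesis, 4 were at least 2-fold lower and 0 higher, with a median of -0.38, below every one of the matched random lists. The 4 were Atf3, Nupr1 (8.24 FPKM in B16 and 1.57 in B16/BL6), the pseudokinase gene Trib3 (19.5 and 6.72 FPKM) and Chac1 (16.4 and 7.35 FPKM), which encodes an enzyme that degrades glutathione. Of 19 hypoxia genes, 14 were below 0, with a median of -0.42 (0.01th percentile). The pyruvate dehydrogenase kinase gene Pdk1 was at 15.9 and 4.53 FPKM and Car12 at 1.45 and 0.0702 FPKM, but Adm and Ndrg1 (23.5 and 52.0 FPKM) were higher in B16/BL6. Of 21 glycolysis genes, 3 were lower and 1 higher, with a median of -0.27 (0.03th percentile). On the TPM scale and with each chromosome centred 4 were lower and 0 higher, and after upper-quartile scaling 3 and 0. The aldolase gene Aldoc was at 11.1 and 2.58 FPKM and the lactate dehydrogenase gene Ldhb at 46.0 and 95.9 FPKM. Eno1, at 4.32 and 0.657 FPKM, and Gapdh, at 0.531 and 0.561 FPKM, had values far below the usual abundance of these enzymes' transcripts. Both genes have processed pseudogenes, and how reads shared with them were assigned is not given in the sources used here, so these values are uncertain and the cause of their low level was not tested. The 15 genes of the unfolded protein response were within 2-fold, with a median of 0.22 (84.8th percentile). It was 0.055 (86.4th percentile) on the TPM scale and 0.107 (49.2nd percentile) with each chromosome centred. Of 12 heat shock genes, Hspb8 was higher and Hspb1, at 2.22 FPKM in B16, was listed at 0 in B16/BL6. Their median was 0.05 (35.3rd percentile), or -0.12 (29.0th percentile) on the TPM scale.

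Markers of other cell types were few. None of 14 keratinocyte and epithelial markers and none of 6 Y-linked genes reached 1 FPKM in either library. Of 18 leukocyte markers, 6 reached 1 FPKM, and S100a8 was at 0.492 FPKM in B16 and 2.68 in B16/BL6, while the pan-leukocyte gene Ptprc was at 0.0180 and 0.0814 FPKM. Their median was 0.26 (88.5th percentile), or -0.09 (64.1st percentile) on the TPM scale. Of 12 endothelial markers, Egfl7 (15.8 and 89.9 FPKM) and Eng (126 and 167 FPKM) reached 1 FPKM, and Pecam1 was at 0.0298 FPKM in B16 and listed at 0 in B16/BL6. Of 21 cancer-testis and germline genes, Rhox5 (0.306 and 1.94 FPKM) and Xlr3a (2.01 and 3.19 FPKM) reached 1 FPKM. Of 5 measured histone genes of the replication-dependent kind, 1 was higher, Hist1h4i at 2.75 and 7.74 FPKM. The histone median was -0.21 (19.5th percentile), or 0.01 (83.6th percentile) on the TPM scale. The 17 housekeeping genes were within 2-fold, with a median of -0.04 (4.98th percentile), and Ppia, at 1.03 and 0.155 FPKM, is uncertain too. In all, 11 of the 27 lists with a percentile lay in the lowest or highest 2.5% of matched random lists, where 1.4 would be so by chance if genes were independent. In a simulation with changed genes and a shifted chromosome, 4 of 24 other lists were so. Some of these lists held shifted members, so this is not a rate for unchanged lists.

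**Figure D2:**
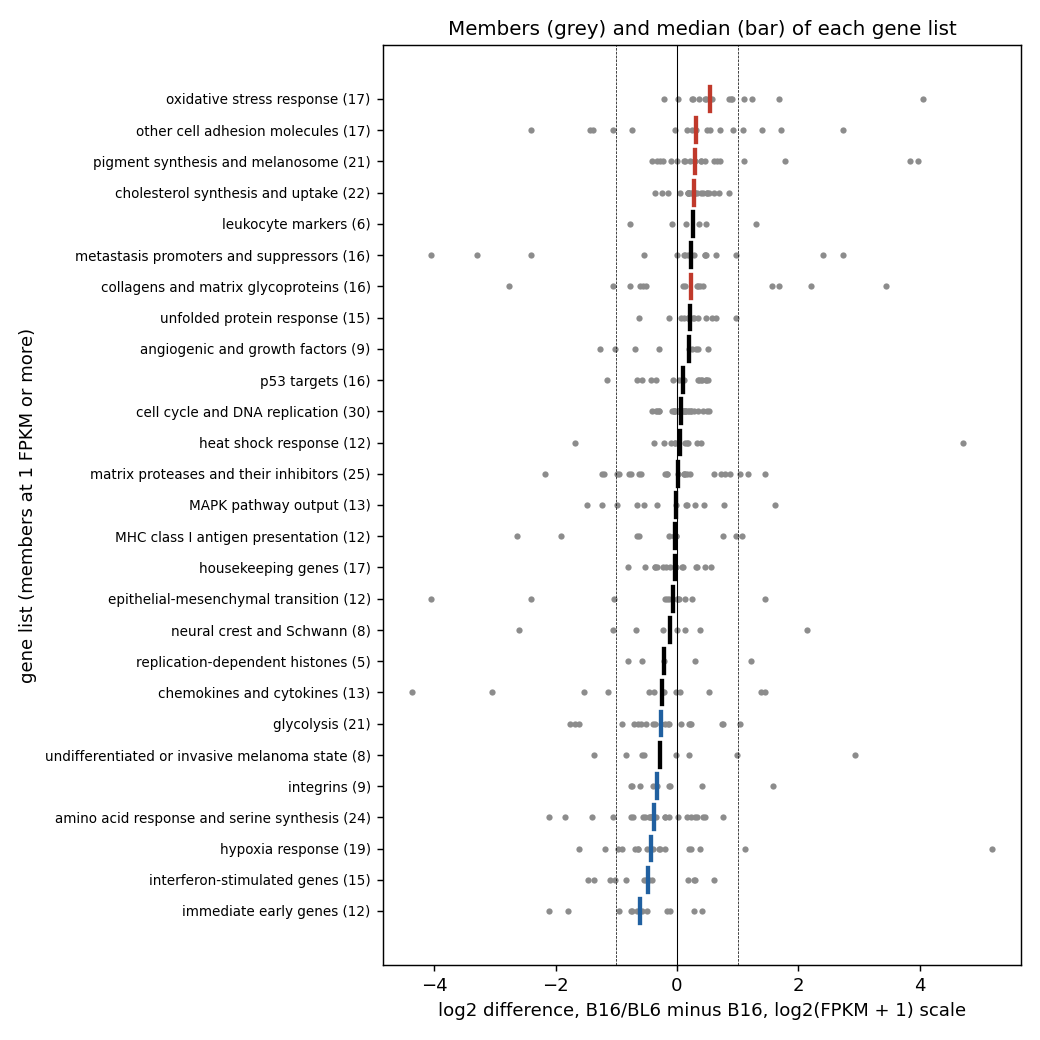
Log2 difference (B16/BL6 minus B16, log2(FPKM + 1) scale) of each measured member (grey points) and the median (bar) of the 27 gene lists with at least 5 members at 1 FPKM or more; the number of members is in parentheses, and dashed lines mark 2-fold. Red and blue bars mark medians in the highest and the lowest 2.5% of matched random lists, with oxidative stress highest at 0.545 and immediate early genes lowest at -0.62.

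Along the genome, the genes of some chromosomes differed together. On chromosome 10, 83.3% of 528 expressed genes were higher in B16/BL6, with a median log2 difference of 0.41, or 1.33-fold. On chromosome 13, 20.2% of 376 genes were higher and the median was -0.32, and on chromosome 18, 23% of 269 genes were higher and the median was -0.295. After gene positions were shuffled 100 times, the farthest chromosome median from 0 was 0.08. Smaller medians beyond that value were found on chromosomes 6 (0.182, 70.0% of genes higher), 12 (0.165, 69.4%), 3 (0.156, 61.1%), 14 (0.136, 63.9%) and 11 (-0.098, 41.3%). All chromosome medians and shares of higher genes are given on the deposited scale only. The TPM scale moved the median of all genes by -0.164, close in size to the medians of chromosomes 6, 12, 3 and 14. Whether the medians of those chromosomes stay above 0 on the TPM scale was not tested. All 49 windows of 40 genes on chromosome 10 had a median above 0, and all 23 on chromosome 18 had one below 0. Chromosome 14 held both directions, from -0.58 at its start (7817921 to 20734570) to 0.41 farther along. Of 993 windows, 93 lay farther from 0 than any window in the shuffles, 30 of them on chromosome 10, 21 on chromosome 13, 13 on chromosome 11, 8 on chromosome 14, 7 each on chromosomes 3 and 8, 5 on chromosome 18 and 1 each on chromosomes 6 and 12. Those on chromosomes 3 and 8 were above 0, up to 0.43 and 0.41, and those on chromosome 11 were below 0, down to -0.46. The highest window lay at the end of chromosome 10 (120781100 to 128048637), with a median of 0.63, against 0.33 for the farthest window in any shuffle.

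**Figure D3:**
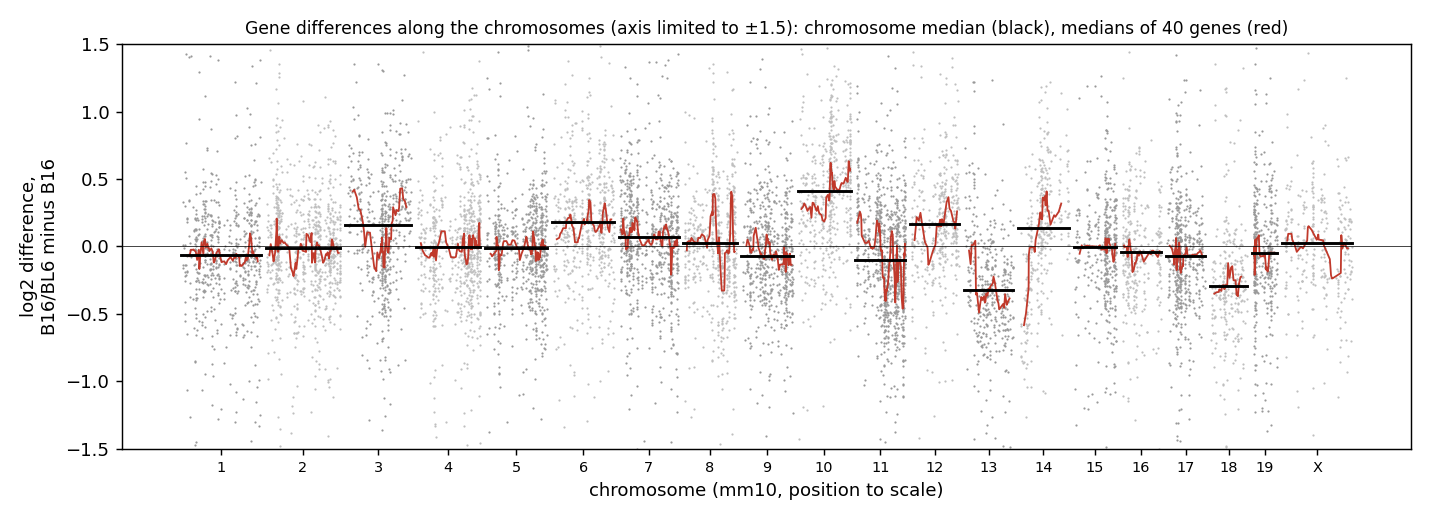
Log2 difference (B16/BL6 minus B16, log2(FPKM + 1) scale; y axis limited to ±1.5, so genes beyond it are not drawn) of each expressed gene (grey points) against its position on the mm10 chromosomes (x axis, to scale), with the median of each chromosome in black and medians of windows of 40 genes in red. Chromosome 10 lies above 0 over its length (median 0.41), and chromosomes 13 and 18 lie mostly below (medians -0.32 and -0.295).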

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

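Only the chromosome-centred alternative was chosen after seeing the data. With 1 library per line, no replicate could be left out and the error of each difference is unknown. No paired analysis was possible because each line had a single library. The count of lower genes was 511 with a pseudocount of 0.1, 118 with one of 5, 212 with a minimum of 5 FPKM and 583 on the TPM scale, against 338, and the count of higher genes was 151 with a pseudocount of 5, against 354; the share of higher genes among the 2-fold differences was 51.2% as deposited and 38.8% on the TPM scale. Spearman's rho was 0.961 without a minimum and 0.930 with a minimum of 5 FPKM. The collagen list's median changed sign on the TPM scale (-0.032), which shifts the median of all genes by -0.164, and it stayed above most matched lists there (85.3rd percentile); it left the outer percentiles on that scale and with pseudocounts of 0.1 (0.232) and 5 (0.156), without a minimum (0.020) and with upper-quartile scaling (0.179). The pigment list left them with a pseudocount of 0.1 (0.297), a minimum of 5 FPKM (0.294) and on the TPM scale (0.126), and the integrin list without a minimum (-0.109), with a minimum of 5 FPKM (-0.227) and on the TPM scale (-0.399). Other lists entered the outer percentiles: the invasive melanoma state without a minimum (-0.326), with a minimum of 5 FPKM (-0.541) and on the TPM scale (-0.730), though it was -0.145 (18.3rd percentile) chromosome-centred, metastasis genes without a minimum (0.160) and against unmatched lists (0.232), p53 targets with a minimum of 5 FPKM (0.355), chemokines on the TPM scale (-0.531) and chromosome-centred (-0.362), and, chromosome-centred, MAPK output (-0.231) and neural crest genes (-0.256). The cause was not tested for any of these. The other 8 lists beyond the outer percentiles (oxidative stress, cholesterol, other adhesion molecules, immediate early, interferon, amino acid response, hypoxia and glycolysis) stayed there, on the same side, under each alternative run. Over the 129 named genes and the pseudocounts, scalings and centring, 662 values moved by less and 112 by more than 1 standard deviation of all genes' differences, 51 of them with a pseudocount of 5, 44 with one of 0.1 and 17 on the TPM scale, and 0 genes with a 2-fold difference changed sign. In place of 93 of 993 windows of 40 genes, 16 of 1033 windows of 20 genes and 160 of 913 windows of 80 genes lay beyond the farthest window of any shuffle. Keeping the highest of several values per symbol gave nothing to compare, since no symbol was repeated.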

Other observations

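Of the tests in this part, the shuffle of gene positions, the size of the GC and length correction and the set of genes gained in B16/BL6 as a check on the CpG test were chosen after the results they bear on were seen, and the patterns and the genes of this paragraph were chosen after their values were seen. The abundant iron-storage genes stood out among genes outside the lists. Fth1, the ferritin heavy chain gene, was at 2244 FPKM in B16 and 6235 FPKM in B16/BL6, and Ftl1, the light chain gene, at 2719 and 7820 FPKM, but both have many processed pseudogenes, so these values are uncertain. Of 3 picked genes of retinoid and aldehyde metabolism, not a test of that class, the alcohol dehydrogenase gene Adh1 stood at 0.483 and 10.3 FPKM, Cyp26b1, which encodes a retinoic acid hydroxylase, at 1.41 and 16.4 FPKM, and Aldh1a7 was listed at 0 in B16 and at 8.42 FPKM in B16/BL6. The glutathione conjugate exporter gene Abcc2 was at 1.15 and 17.7 FPKM and the gamma-glutamyl transferase gene Ggt1 at 0.0499 and 7.65 FPKM. The 73 ribosomal protein genes had a median log2 difference of 0.16 as deposited and 0.00 on the TPM scale. Xist and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0 in both libraries.

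The higher oxidative stress genes suggest a hypothesis, that targets of the transcription factor Nrf2 are more expressed in the B16/BL6 culture. A second list of 34 Nrf2 targets, sharing no gene with the first, was drawn up after the first list's result but before the values of its members were examined. Of its 31 expressed members, 23 were above 0, among them Mgst1 (40.8 and 107 FPKM), Blvrb (77.8 and 186 FPKM) and Prdx6 (105 and 215 FPKM), 1 was at least 2-fold lower, Cbr1 (27.7 and 9.12 FPKM), and the median log2 difference of 0.51 lay at the 100th percentile of matched random lists. The shift of whole chromosomes was argued against for the first list, since it stayed at the 100th percentile with each chromosome centred. The second list was not centred. Centring does not remove a shift of part of a chromosome. Nqo1, Osgin1 and Hmox1 lie on chromosome 8, whose median was 0.024. Yet chromosome 8 held 7 windows beyond any in the shuffles (0.352 to 0.407), so a shift of part of a chromosome stays open. The line and its medium both stay open, since this design cannot separate them. The transcripts of Nfe2l2, which encodes Nrf2 (72.3 and 53.4 FPKM), and of its repressor Keap1 (23.7 and 23 FPKM) were not higher in B16/BL6. These transcript levels do not give the activity of the Nrf2 protein, which was not measured.

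The joint difference of the genes of chromosomes 10, 13 and 18 may come from a different number of copies of these chromosomes in the lines. Chance placement was argued against, since 0 of 100 shuffles reached the real value of 0.41 (highest other 0.08). A bias of GC content or transcript length was argued against, since with those trends removed the medians of chromosomes 10, 13 and 18 were 0.414, -0.314 and -0.274, and the amounts removed (-0.095 to 0.170 per gene) were smaller than the medians. A copy number difference would act on genes of every level, and the median of chromosome 10 was 0.282, 0.381 and 0.557 among its genes of low, middle and high mean FPKM, in 3 groups of about equal size. These medians were -0.279, -0.375 and -0.321 on chromosome 13 and -0.341, -0.318 and -0.239 on chromosome 18, so the order by level was not shared, and its cause was not tested. The chromosomes were picked for their medians, and 83.3% of the genes of chromosome 10 were higher. That left little room for a group near 0, so the medians by level add little weight to a copy number difference. No DNA was measured here, and regulation of whole chromosomes stays open.

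Some genes were listed at 0 in 1 library and at 5 FPKM or more in the other, 21 small RNA genes and 15 others, such as Adm, Galnt6, Foxr2 and Taf9b. For the 15 others, the value in the library that listed them rested on a median of 193.8 fragments, by a depth estimate whose range was set after the values were seen. Their choice at 5 FPKM or more, with a median length of 2066 bases, left no room for a low median, so the median was no test. The lowest of the 15 estimates was 28.7 fragments, and the depth of B16/BL6 was about 1.10 times that of B16. An equally expressed gene would then have more than a few fragments in the other library too. As far as the approximate depth holds, this argues against sparse sampling as the source of these zeros. Reads passing to an overlapping gene on the same strand were argued against as the general cause, since 2 of the 15 (13.3%) had such a neighbour, 0.57 times the share among genes at 5 FPKM or more in both libraries (23.6%), although Snhg9 and Snora78 may have exchanged reads. A difference between the lines stays open, and so does a failed estimate. For the small RNAs the estimate was 122.4 fragments, but their median length of 130 bases is short for the kind of fragments such kits make, so the effective length behind it is unknown and the question stays open.

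Another hypothesis was that genes lost in B16/BL6 have promoters rich in CpG, as genes silenced by DNA methylation often do. The 30 genes at 5 FPKM or more in B16 and under 1 FPKM in B16/BL6, among them Tagln2, Isyna1, H2-K1 and Pycard, had a median observed to expected CpG ratio of 0.62 in the first 300 bases of their transcripts, at the 1.44th percentile of lists matched on expression (median 0.75). The 37 genes with the opposite pattern had a median of 0.60, at the 0.34th percentile, so genes off in either line lay low against this reference, and the test does not bear on silencing.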
